A study of Homo sapiens with 6 samples.

How the data were processed

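RNA from RKO, a human colon carcinoma cell line, was measured in 6 libraries, 3 of cells with wild-type GSK3B and 3 of cells described as GSK3B knockouts. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made from polyadenylated RNA with a VAHTS Universal kit, and paired-end reads of 150 bp were sequenced on an Illumina instrument. The deposited values are whole-number counts per gene symbol, not normalized, with 1 table per library. Per the submitters' processing notes, the genome build was hg38 and the tools included TopHat, limma and edgeR, named without versions or roles. The counting program, its gene annotation, its strand setting and its treatment of reads that match several genes are not given in the sources used here. The labels do not say how the knockout was made, whether the cells were a clone or a pool, or whether the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

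Each table had 28278 gene symbols, of which 8380 were at 0 in all 6 libraries, and 0 blank or total entries. FBL, NDUFS1, FDFT1, HYOU1, TJP1, ZYX and EEF1B2, genes that dividing cells generally use, were among those listed at 0, so a 0 in these tables was not read as absence of expression. Total counts ran from 32379369 to 33558362 per library and 17319 to 17419 genes had a count. Symbols were matched to GENCODE 29 by name and, where that failed, by gene identifier or older symbol, and 26202 matched. Coordinates are those of GENCODE 29 on hg38. The share of tested genes with a transcript GC content was 95.8%, taken from the longest transcript of each gene.

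The groups came from the sample titles. The libraries were compared first by Pearson correlation of log2 CPM and by a chi-square test of the counts of each pair within a group. The chi-square per degree of freedom was 3.16 to 9.71 within groups, so no pair differed by as little as sampling noise and each library counted as 1 replicate. Such a spread does not show that the libraries came from separate cultures.

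Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (minimum count 10, minimum total 15) were kept, which left 14409. Libraries were scaled by TMM, a quasi-likelihood model with group as its only term was fitted with robust estimation, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are TMM-scaled, and standard errors of log2 fold changes were derived from the fold change and the F statistic. GSK3B and GSK3A were also compared by a two-sided exact permutation test of log2 CPM, which with 3 against 3 libraries cannot give a p below 0.1.

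Before the data were examined, 36 gene lists were fixed. The 32 lists with 5 or more tested genes were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2. Their p-values were adjusted over the lists. The same test with a correlation estimated from the libraries and fry were run beside it; fry asks whether a list's genes move, on balance, one way and does not compare the list with other genes. Counts of changed members are given over all tested genes and also adjusted over the list alone.

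The rule for the named genes was also fixed before the data were examined. It took GSK3B and GSK3A, then the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 5 CPM and no overlap between the groups. It passed over uncharacterised, antisense, microRNA, pseudogene and readthrough symbols. It added up to 4 changed members with the largest change from each list described. Where a list had no changed member, it took those with the highest mean expression. It also added the 4 smallest p-values not already named. Genes named outside the rule are said to be so, and a few that the rule took are not reported here.

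Alternatives fixed beforehand were RLE scaling, scaling by library size alone, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, estimation without the robust option, and the other list tests. Chosen after seeing the data were a correction for GC content (a spline with 5 degrees of freedom per library, used as an offset), this correction with the replicate block, and leaving out ribosomal RNA genes and the 125 genes whose counts were identical to those of another gene. The map of fold changes along the chromosomes, 2 further gene lists and the matching by older symbols were also chosen after seeing the data.

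The tests were tested on simulated data drawn from the real means, spread and library sizes of the knockout against wild-type comparison, with 200 genes changed. Of 14316 genes tested, the quasi-likelihood test recovered 67.3% of those given the smallest change, with a mean estimated log2 fold change of 0.33 in size, 78.0% of those changed 1.5-fold, 89.8% of those changed 2-fold and 94.0% of those changed 3-fold, with 8 false calls. With the GC trend of the real libraries added, 14308 genes were tested. Of those given the smallest change (0.31 in size) 54.0%, or 27 genes, were recovered. Of those changed 1.5-fold, 2-fold and 3-fold, 39, 42 and 47 genes were recovered. There were 32 false calls beside these, a larger share of the calls than the adjusted p threshold allows. With the GC correction there were 15 false calls in 13724 genes, beside 36, 38, 38 and 48 recovered genes from the smallest to the largest change. That share is smaller, but also above what the threshold allows. The main counts of changed genes come from the uncorrected test, so more of them may be false than the threshold states. Calls after the GC correction have the same limit to a lesser degree. In a separate simulation camera found a list shifted by 0.20 on the log2 scale (adjusted p = 4.86e-15) and called 0 of the 31 others. Correlation between genes is not among the stated settings of the simulated data. This result therefore does not test the preset correlation, and does not vouch for lists whose genes move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.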

Results

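Messenger RNA was sequenced from RKO cells, a line derived from a human colon carcinoma, in 3 libraries of cells with wild-type GSK3B and 3 of GSK3B knockout cells. GSK3B encodes a serine/threonine kinase that phosphorylates beta-catenin, glycogen synthase and many other proteins. The series was made to find which transcripts depend on GSK3B. Total counts were 32721641, 32565829 and 33052404 in wild-type replicates 1 to 3, and 33023291, 32379369 and 33558362 in knockout replicates 1 to 3. Depth therefore differed little between the groups, and EEF1A1, the gene with the most counts in each library, took 1.75% to 1.83% of them. Ribosomal RNA genes took 3.20% to 3.58%.

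GSK3B itself was lower in every knockout library than in every wild-type library. Its level was 99.0, 97.6 and 91.4 CPM in wild-type replicates 1 to 3 and 46.0, 47.5 and 47.1 CPM in knockout replicates 1 to 3. The knockout level was 48.8% of the wild-type level (95% interval 44.3 to 53.7), a log2 fold change of -1.04 ± 0.05 (SE, n = 3 per group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.88e-12). The two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries can give. GSK3B lies on chromosome 3, from 119821323 to 120094417 on the minus strand in hg38. The counts cover the whole gene and do not show which part of the transcript was present. GSK3A, the paralog of GSK3B on chromosome 19 (42230186 to 42242625), had 84.5 ± 4.57 CPM in wild-type and 86.4 ± 2.29 CPM in knockout libraries (SD, n = 3). It did not pass the test, at 102% of wild type (95% interval 93.0 to 112; exact permutation p = 0.7). GSK3A shares exon positions with another annotated gene.

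Many genes differed between the groups, most of them by small amounts. Among the genes the naming rule took, the matrix protease gene MMP3 rose most, and the signal transducer gene SMAD3 and the keratin genes KRT7 and KRT80 fell most. Of 29 genes of hypoxia and glycolysis 23 fell and 6 did not pass, and the list passed camera with its preset correlation but not with an estimated one (adjusted p = 1.91e-16 and 0.185). In edgeR's quasi-likelihood test 1951 of 14409 genes changed at an adjusted p under 0.05, 917 higher and 1034 lower in the knockout. The median size of these changes was 0.25 on the log2 scale, and 93 genes changed 2-fold or more, 9 up and 84 down. In simulated data with the libraries' GC trend, false calls of this test exceeded the share that its threshold allows. They also did, by less, with a correction for GC content. The groups did not overlap in 4512 genes (31.3%), where chance gives 10%. The share of changed genes that were higher was 47.0%, but 34.6% with scaling by library size alone (649 higher, 1229 lower). It was 57.8% after a correction for GC content chosen after seeing the data (1633 higher, 1192 lower). The count of changed genes fell to 1072 without wild-type replicate 2, and to 1094, 950 and 1205 without knockout replicates 1, 2 and 3. It rose to 2531 without wild-type replicate 1 and to 2046 without wild-type replicate 3.

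Among the rises, MMP3, which encodes a secreted protease of the extracellular matrix, went from 5.50 ± 0.55 to 16.0 ± 0.53 CPM (SD, n = 3), 2.90-fold (log2 fold change 1.54 ± 0.10 SE). MMP1, an interstitial collagenase gene beside it on chromosome 11, rose 1.69-fold. Both share exon positions with the pseudogene WTAPP1, which leaves their counts uncertain where reads were shared. COL6A3, a collagen VI chain, rose 1.92-fold, and SPP1, which encodes the secreted protein osteopontin, rose 1.44-fold. SH3TC2 rose 2.12-fold, TMCC3 1.60-fold and KBTBD8 1.40-fold. HSPH1, a heat shock chaperone, rose 1.51-fold from 84.9 ± 8.03 to 129 ± 3.78 CPM. PDCD1LG2, which encodes the PD-1 ligand PD-L2, rose 1.51-fold, and AMOTL1, an angiomotin family gene, rose 1.44-fold. Adjusted p-values of these 10 genes in edgeR's test were at most 0.00437, that of PDCD1LG2.

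Among genes with a mean of at least 5 CPM and symbols that the naming rule admits, the largest fall was that of SMAD3, a transducer of TGF-beta signals, from 14.1 ± 0.74 to 4.09 ± 0.50 CPM (SD, n = 3; log2 fold change -1.79 ± 0.11 SE). The keratin genes KRT7 and KRT80, neighbours on chromosome 12, changed by -1.75 and -1.71 on the log2 scale. KRT7 shares exon positions with its antisense gene KRT7-AS, named here after its values were seen, which changed by -1.81. Without a stated strand setting the reads of that pair cannot be told apart. EPPK1, which encodes the keratin-binding protein epiplakin, changed by -1.49, with 8.66 ± 2.37 CPM in wild type and 3.08 ± 0.95 CPM in knockout. ENAH, an actin regulator, changed by -1.25 and COBL, an actin nucleator, by -1.04. TP53I11 changed by -1.10, the kinase gene PLK2 by -1.06, RASSF8 by -1.04 and PELI2, a ubiquitin ligase gene, by -1.04. The genes with the smallest p-values not already named were NDRG1 (427 ± 12.8 to 285 ± 9.19 CPM), the glucose transporter gene SLC2A1 (175 ± 2.35 to 114 ± 3.25 CPM), ARHGAP29 (181 ± 12.5 to 113 ± 2.61 CPM) and the enolase gene ENO2 (298 ± 8.88 to 207 ± 2.79 CPM), all lower in the knockout.

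**Figure D1:**
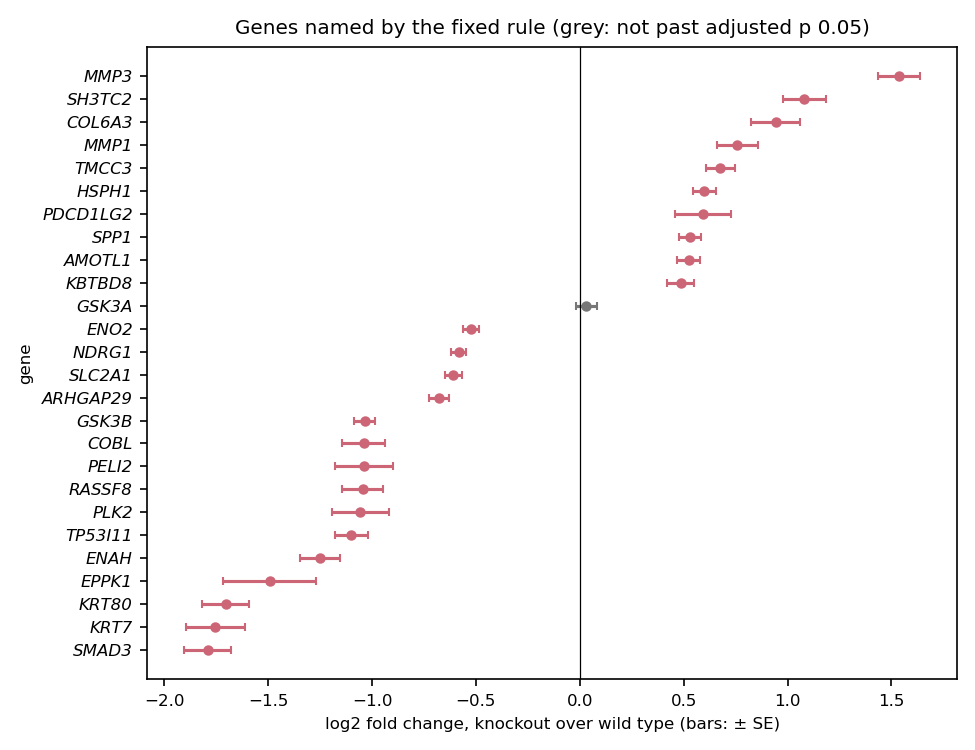
Log2 fold change of knockout over wild type (horizontal axis) for the genes named by the fixed rule (vertical axis), 3 libraries per group, with bars of 1 standard error. MMP3 lies farthest to the right at 1.54, SMAD3 farthest to the left at -1.79, GSK3B at -1.04 and GSK3A, in grey, near 0.

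Genes of hypoxia and glycolysis formed the list with the strongest shift. Of its 29 tested members 23 fell, 0 rose and 6 did not pass the test, and 25 fell when adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 26 lower and 1 higher, and DESeq2 and limma-voom called 23 and 24 lower and 0 higher. CA9, a carbonic anhydrase gene, fell from 16.7 ± 0.94 to 8.72 ± 0.67 CPM (SD, n = 3), ANKRD37 from 4.99 ± 0.15 to 2.70 ± 0.48 CPM and PFKFB4, a regulator of glycolytic flux, from 82.1 ± 3.15 to 52.2 ± 3.56 CPM. SLC2A1, NDRG1 and ENO2, named above, are members, as is VEGFA, named below with the integrated stress response. The list's median log2 fold change was -0.37 (camera, adjusted p = 1.91e-16; adjusted p = 0.185 with an estimated correlation). After the GC correction the median was -0.34 (adjusted p = 4.10e-12; adjusted p = 0.0395 with an estimated correlation).

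Of 29 tested target genes of MYC and ribosome biogenesis 14 rose, 1 fell and 14 did not pass, also when adjusted over the list alone. UTP20, a component of the small-subunit processome, rose 1.38-fold, and the nucleolar genes NOP58 and NOP56 rose 1.20-fold and 1.16-fold. The member that fell was LDHA, the lactate dehydrogenase gene that the hypoxia list also holds, from 1338 ± 49.5 to 1026 ± 6.56 CPM. The list's median log2 fold change was 0.12 (camera, adjusted p = 1.58e-05; adjusted p = 0.166 with an estimated correlation). After the GC correction 21 members rose and 1 fell, with a median of 0.19 (adjusted p = 3.03e-07; adjusted p = 0.0529 with an estimated correlation). MYC itself fell, with a log2 fold change of -0.22 ± 0.03 (SE). Of 40 tested cytosolic ribosomal protein genes 12 rose and 1 fell (13 and 2 adjusted over the list alone), among them RPS27, RPS7, RPS24 and RPL6 with log2 fold changes of 0.22, 0.20, 0.19 and 0.13. As a list they did not pass (camera, adjusted p = 0.0574), but did after the GC correction (adjusted p = 0.0280, and 0.441 with an estimated correlation). They also passed as a list without wild-type replicate 3 (camera, adjusted p = 0.0240), but not in the other fits without 1 library.

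Of 19 tested canonical Wnt/beta-catenin target genes, among them negative feedback regulators of the pathway, 7 fell, 0 rose and 12 did not pass, the same counts as when adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 8 lower and 1 higher, and DESeq2 and limma-voom each called 6 lower and 0 higher. BMP4 changed by -0.99, NOTUM by -0.70, AXIN2 by -0.59 and NKD1 by -0.32 on the log2 scale. Both BMP4 and NOTUM were low, at 3.62 ± 1.23 and 2.13 ± 0.30 CPM in wild type (SD, n = 3). In the knockout they had 1.82 ± 0.25 and 1.31 ± 0.24 CPM. The lowest wild-type value of BMP4, 2.25 CPM in replicate 3, lay close to its highest knockout value, 2.10 CPM. AXIN2 had 5.33 ± 0.22 CPM in wild type and 3.54 ± 0.88 CPM in knockout (SD, n = 3). The list's median was -0.22 (camera, adjusted p = 7.56e-04; adjusted p = 0.185 with an estimated correlation), and -0.07 after the GC correction (adjusted p = 0.0256; adjusted p = 0.226 with an estimated correlation), when 6 fell and 1 rose. NOTUM no longer passed after that correction (edgeR, adjusted p = 0.0741). Among 31 Wnt pathway components 2 rose and 7 fell (3 and 7 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.187). FZD1, TNKS2 and CTNNBIP1 fell, with log2 fold changes of -0.48, -0.40 and -0.35, as did WNT11 at -0.71, which no longer passed after the GC correction (edgeR, adjusted p = 0.0523).

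Of 27 tested p53 target genes 11 fell and 0 rose (13 and 1 adjusted over the list alone). At an unadjusted p under 0.05 edgeR had 14 lower and 2 higher, and both DESeq2 and limma-voom called 11 lower, with 1 and 0 higher. Besides PLK2, these included TP53INP1 at -0.50, the DNA damage recognition gene DDB2 at -0.38 and BBC3, which encodes the pro-apoptotic protein PUMA, at -0.38. The list's median was -0.12 (camera, adjusted p = 7.56e-04; adjusted p = 0.185 with an estimated correlation), and -0.05 after the GC correction (adjusted p = 0.00409; adjusted p = 0.174 with an estimated correlation).

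Target genes of NF-kappaB also passed the list test, less firmly, with 8 of 23 members lower and 2 higher (9 and 3 adjusted over the list alone). BIRC3, TNFAIP3 and NFKBIA fell, with log2 fold changes of -0.49, -0.41 and -0.30, while BIRC2 rose by 0.36. The median was -0.14 (camera, adjusted p = 0.0250; adjusted p = 0.204 with an estimated correlation, and 0.178 after the GC correction). Over the fits without 1 library it ran from -0.26 without knockout replicate 1 to -0.15 without wild-type replicate 2. The list did not pass without wild-type replicate 1 or 2 or knockout replicate 3 (adjusted p = 0.0594, 0.0684 and 0.0507). Of 17 YAP/TAZ target genes 4 fell and 1 rose, the same counts as when adjusted over the list alone. CCN1, MYOF and ARHGEF17 fell, at -0.48, -0.44 and -0.41, and AMOTL1 rose. The median was -0.07 (camera, adjusted p = 0.0250; adjusted p = 0.204 with an estimated correlation, and 0.135 after the GC correction). This list did not pass without wild-type replicate 1 or knockout replicate 1 or 3 (adjusted p = 0.0747, 0.0618 and 0.110).

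**Figure D2:**
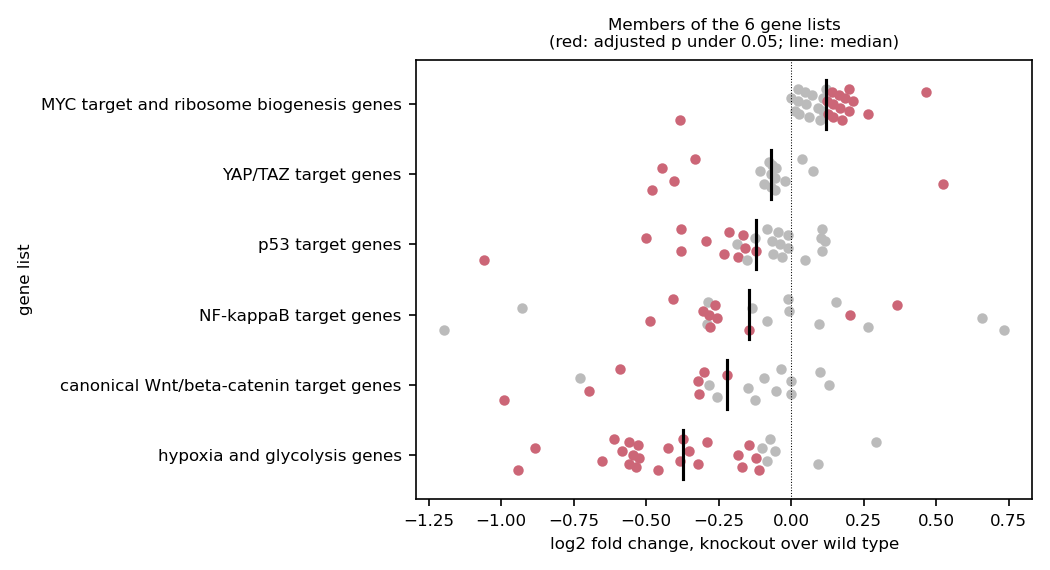
Log2 fold change of knockout over wild type (horizontal axis) of each tested member of the 6 lists that passed camera with its preset correlation (vertical axis). Each point is a gene, red where its adjusted p was under 0.05, and the black line is the list's median, lowest for hypoxia and glycolysis at -0.37 and highest for MYC targets and ribosome biogenesis at 0.12.

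Some members changed in lists that did not pass as a whole. Among 24 genes of the integrated stress response 5 fell and 3 rose; DDIT4, ATF3, CHAC1 and VEGFA fell, with log2 fold changes of -0.77, -0.69, -0.67 and -0.42 (list, camera, adjusted p = 0.169). Of 10 epithelial genes 2 fell, EPCAM from 3.43 ± 0.95 to 1.07 ± 0.04 CPM and the desmosomal gene DSP from 20.1 ± 1.47 to 9.88 ± 0.79 CPM (SD, n = 3; list adjusted p = 0.0621). The epithelial list passed camera without knockout replicate 1 or 2 (adjusted p = 0.0291 and 0.0399), but not in the other fits without 1 library. After the GC correction its median was 0.05 (camera, adjusted p = 0.665). Of 16 mesenchymal genes 3 fell, TPM2 and CALD1 at -0.43 and -0.40 and COL1A1, which did not pass without wild-type replicate 3 (list adjusted p = 0.231). Of 19 NRF2 target genes 3 rose, SLC7A11, GCLM and FTL at 0.37, 0.24 and 0.13, and TXNRD1 fell at -0.25 (list adjusted p = 0.0549, and 0.0120 after the GC correction; adjusted p = 0.209 with that correction and an estimated correlation). The NRF2 list also passed camera with the replicate block, without wild-type replicate 3 and on ranks (adjusted p = 0.0480, 0.0285 and 0.0474). It did not pass in the other fits without 1 library. Of 20 genes of glycogen metabolism PPP1R3B and PGM1 fell, at -0.41 and -0.20 (list adjusted p = 0.128). Of 22 antigen presentation genes CD274, which encodes PD-L1, rose from 255 ± 15.7 to 354 ± 6.38 CPM and TAP2 rose by 0.17 (list adjusted p = 0.797). Adjusted over the list alone, B2M, HLA-E and HLA-F, named here after their values were seen, were also called, lower, at -0.10, -0.12 and -0.23. Of 24 cholesterol synthesis genes 4 fell and 2 rose, with the transcription factor gene SREBF2 at -0.23 and MSMO1 at -0.16 (list adjusted p = 0.316). Adjusted over the list alone, 4 mesenchymal genes fell and 4 NRF2 targets rose, and the counts of the stress response, epithelial, glycogen and cholesterol lists were the same.

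Proliferation genes moved little. Of 30 genes of mitosis 3 rose and 1 fell, with ANLN at 0.18 and UBE2C at -0.15 (list, camera, adjusted p = 0.432), and of 30 replication and E2F target genes 4 rose and 1 fell, with GINS3 at 0.31 and TK1 at -0.25 (adjusted p = 0.231). Of 26 interferon-stimulated genes SAMD9 rose by 0.26 and ISG15 changed by -0.30 (adjusted p = 0.797). Of 23 ERK output genes 4 rose and 5 fell, with EGR1 at 0.25 and DUSP6 at -0.30 (adjusted p = 0.436). In the lists of 7 Hedgehog and 7 intestinal differentiation genes 0 members passed edgeR, DESeq2 or limma-voom, and 0 and 1 had an unadjusted p under 0.05 in edgeR. After the GC correction the Hedgehog gene KIF7, named here after its values were seen, passed at 0.18 (edgeR, adjusted p = 0.0322). PTCH1 stood at -0.08 and CA2 at -0.15. Adjusted over the list alone, 6 replication and E2F targets rose and 2 fell, 4 ERK output genes rose and 6 fell, and the other counts were the same.

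Of 31 lysosome and autophagy genes 4 rose and 2 fell, with LAMP1 at 0.25 and GABARAPL1 at -0.64 (camera, adjusted p = 0.268, and 0.0452 after the GC correction; adjusted p = 0.226 with that correction and an estimated correlation). Of 24 immediate-early genes 3 rose and 4 fell, with FOS at 0.42 and BTG2 at -0.29 (adjusted p = 0.231). Of 30 apoptosis regulators 3 rose and 5 fell, with CYCS, the cytochrome c gene, at 0.22 and BMF at -0.69 (adjusted p = 0.768). BHLHE40 fell at -0.44 and SKI rose at 0.16 among 18 TGF-beta response genes (adjusted p = 0.270), and HES4 and DTX4 fell at -0.41 and -0.40 among 14 Notch pathway genes (adjusted p = 0.344). ACSL4 rose by 0.23 among 22 ferroptosis genes, of which 3 rose and 1 fell (adjusted p = 0.370). ELOVL6 rose by 0.14 and ACSS2 fell at -0.22 among 12 fatty acid synthesis genes (adjusted p = 0.370). COX6C rose by 0.21 and CYC1 fell at -0.15 among 32 nuclear genes of oxidative phosphorylation, of which 2 rose and 1 fell (adjusted p = 0.768). CYC1 no longer passed after the GC correction, at -0.05 (edgeR, adjusted p = 0.356). In the unfolded protein response list EDEM1 alone of 18 genes passed, at -0.13 (adjusted p = 0.420). Adjusted over the list alone, 5 lysosome and autophagy genes rose and 4 fell, 3 immediate-early genes rose and 5 fell, and 1 TGF-beta response gene rose and 3 fell. The counts of the other lists here were the same.

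Counts of some marker genes of other cell types, picked here after they were seen, lay mostly in 1 library. DCN had 25 of its 26 counts, COL1A2 23 of 24, COL3A1 18 of 20 and COL1A1, less so, 61 of 122 in wild-type replicate 3. LYZ, listed as a leukocyte marker, had 14 of 15 in wild-type replicate 1. COL1A1, PDGFRB and ENG, listed as fibroblast and endothelial markers, fell from 0.94 ± 0.78, 1.92 ± 0.28 and 3.75 ± 0.28 CPM to 0.29 ± 0.08, 0.71 ± 0.13 and 1.92 ± 0.42 CPM (SD, n = 3), though DESeq2 and limma-voom each called only 2 of the 3. Without wild-type replicate 3 COL1A1 stood at -0.72 and no longer passed (edgeR, adjusted p = 0.389), while PDGFRB and ENG, at -1.39 and -0.91, still did (adjusted p = 0.00259 and 0.00313). The comparison without that library had 1022 genes higher and 1024 lower, and 1566 of the 1951 calls kept their direction and call. Of 5 nervous system markers TUBB3 fell at -0.19 (list, camera, adjusted p = 0.630), but stood at -0.10 and did not pass after the GC correction (edgeR, adjusted p = 0.135). The leukocyte-listed genes CD68 and CORO1A, at 749 and 37.1 CPM in wild type, and the cancer-testis gene PRAME, at 80.6 CPM, did not pass the test. After the GC correction CD68 passed at 0.06 (edgeR, adjusted p = 0.0463), and the others did not. PTPRC, the pan-leukocyte gene, was at 0. Mitochondrially encoded genes were not analysed here.

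By correlation, libraries of a group resembled each other more than those of the other group. Pearson's correlation of log2 CPM across genes was 0.993 to 0.995 within groups and 0.991 to 0.992 between them, and the first principal component, with 36.7% of the variance, separated the groups. By the chi-square of their counts per degree of freedom they did not part in the same way, since wild-type replicates 1 and 3 differed by 9.71, more than wild-type replicate 1 did from knockout replicates 1 and 3 (8.84 and 8.68). Wild-type replicate 3 stood apart in its relation of counts to transcript GC content, with a slope of 0.0991 log2 units per 10 points of GC, against -0.0186 and 0.0182 in wild-type replicates 1 and 2 and -0.0388 to -0.0264 in the knockout.

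**Figure D3:**
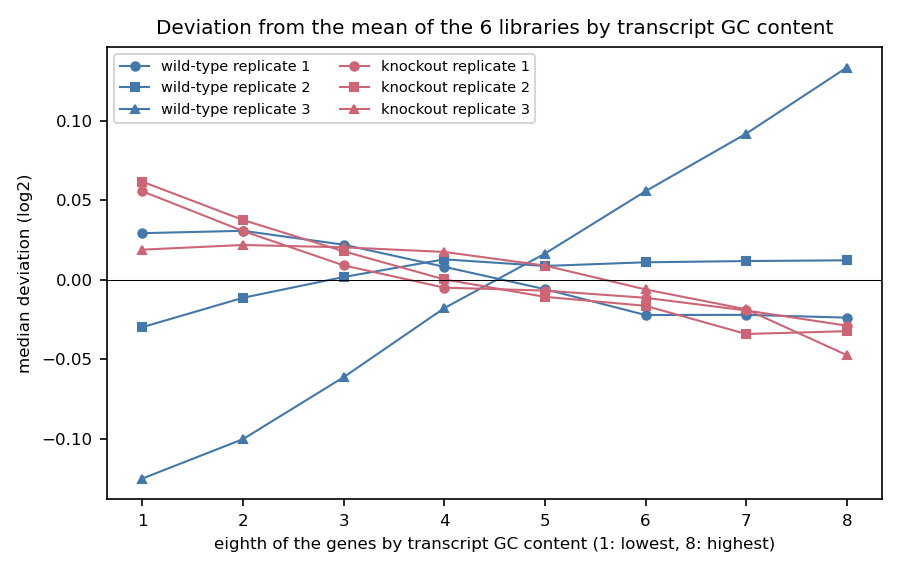
Median deviation of each library from the mean of the 6 libraries, in log2 units (vertical axis), in 8 equal groups of genes ordered by transcript GC content (horizontal axis); blue lines are wild-type and red lines knockout libraries. Wild-type replicate 3 runs from -0.13 in the lowest group to 0.13 in the highest, and at both ends the other 5 libraries lie nearer 0.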

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

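The alternatives with a GC correction or without identical-count genes were chosen after seeing the data. The main counts were 917 genes higher, 1034 lower, 93 changed 2-fold or more and 6 gene lists. Under the GC correction 1633 genes were higher, and 1632 with the replicate block added; 1628 of 1915 changed genes with a GC content kept their call and direction. Genes changed 2-fold or more numbered 61 with DESeq2 and 56 with a filter of 1 CPM, which tested fewer genes. Leaving out 1 library gave 361 to 1259 genes higher, 589 to 1272 lower, 75 to 109 changed 2-fold or more and 4 to 8 lists. With an estimated correlation camera called 0 of 32 lists, with 7 at an unadjusted p under 0.05, and fry called 14. The 26 genes named for their own values kept direction and side of the threshold in 441 of 442 comparisons; GSK3A, not past the threshold, turned to -0.0102 without wild-type replicate 1, in a range of -0.0102 to 0.0727 over the fits without 1 library. The cause was not tested. All of the 26 but GSK3B and GSK3A were picked from these libraries for large changes or small p-values. That they stayed called was therefore nearly assured. Of all 1951 changed genes, 928 to 1770 kept call and direction in the fits without 1 library. The 6 lists kept direction and side of the threshold in 80 of 96 comparisons and lost the call in 16, mostly NF-kappaB and YAP/TAZ targets. Same-numbered libraries deviated with correlations of -0.00406 to 0.0709, and differently numbered ones with -0.0878 to 0.0599. Correlations this small do not show a pairing and cannot exclude one. The second principal component held 18.9% of the variance. On it wild-type replicates 1 to 3 lay at 12.9, -1.79 and -9.07, and knockout replicates 1 to 3 at 11.3, 3.92 and -17.3. The replicate block gave 1080 genes higher and 1113 lower. The pseudocount alternative did not apply to counts.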

Other observations

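The gene groups, the GC and position tests and the hypoxia tests in this part were chosen after the results were seen; the count of splits was planned.

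Some heat shock chaperones were higher in the knockout. Of 20 tested genes of a list made after some of them had been seen to rise, 10 rose, 0 fell and 10 did not pass in edgeR's test (14 higher and 1 lower at an unadjusted p under 0.05; 11 and 0 in both DESeq2 and limma-voom), with a median log2 fold change of 0.14. A test of such a list carries no weight, and none is given. CHORDC1 rose by 0.44, HSPA8 by 0.25, HSPA1A by 0.20, HSPE1 by 0.20 and the co-chaperone gene DNAJB1 by 0.18. HSP90AA1, at 0.25, and HSPB1, at -0.10, did not pass the test. HSF2, a heat shock transcription factor gene looked at together with the chaperones and left off the list, changed by -0.24.

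A second such list, of low-oxygen response genes outside glycolysis, held 18 tested genes, of which 13 fell and 0 rose in edgeR, DESeq2 and limma-voom (15 and 0 at an unadjusted p under 0.05 in edgeR; median -0.34). MIR210HG, the host gene of a microRNA induced by low oxygen, changed by -1.34, BNIP3L by -0.69 and KDM4B by -0.49. The list shares ANKRD37 and KDM3A with the fixed hypoxia and glycolysis list and BHLHE40 with the TGF-beta response list. Their falls are therefore counted again here. Several members of the list had been seen to fall before it was made, so no test of it is given either. In the protocadherin gamma cluster 17 of 22 tested genes were lower and 0 higher in edgeR's test (22 and 0 at an unadjusted p under 0.05), but DESeq2 called 4 lower and limma-voom 14. These genes share their last exons, so the counts are largely 1 signal counted many times.

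The real grouping of the libraries gave 1951 changed genes and the highest of the other 9 splits gave 0 in edgeR's test, with 199 to 810 genes at an unadjusted p under 0.05 against 4034. Of the 10 splits 1, the real one, gave as many, and 10 are too few for a share under 0.05. Each of the other 9 puts libraries of both groups together, which adds the group difference to the spread within them. Their 0 is therefore not a measure of chance alone.

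Changed genes followed transcript GC content. In the eighth of genes with the lowest GC content 262 were higher and 33 lower, and in the highest eighth 26 and 240, with a Spearman correlation across genes of -0.334, genes not being independent replicates. The calls do not come from this trend alone, since 85.0% of those with a GC content kept their call and direction after the correction. The trend itself may come from single libraries, as the GC slope ranged over 0.118 log2 units per 10 points within the wild type, more than the -0.0658 between the groups. An effect of GSK3B loss on GC-rich transcripts was not tested.

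Of 29 hypoxia and glycolysis genes 23 fell in the knockout and 6 did not pass, and the list did not pass camera with an estimated correlation (adjusted p = 0.185) except after the GC correction (adjusted p = 0.0395). GC content does not account for the fall, since the list's median was -0.343 after the correction. The fall does not rest on 1 library, since the weakest median over the 6 fits without 1 library was -0.355. The list medians of the 3 wild-type libraries ranged over 0.0342, and those of the knockout lay at -0.352, -0.378 and -0.334 relative to the wild-type mean. A difference in oxygen supply or cell density between the cultures cannot be told apart from an effect of GSK3B, because the labels record neither and such a difference may follow the groups.

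Genes at the far end of the long arm of chromosome 1 were slightly higher in the knockout. Between 227563543 and 248919946 lay 74 expressed genes with a GC-corrected median log2 fold change of 0.13, 61 of them above 0, against 0.01 for 346 genes nearer the centromere. The edge of this block was set after seeing the data. Some of the 74 genes overlap in position, such as MIR3620 with ARF1, COA6-AS1 with COA6, and TSNAX-DISC1 with TSNAX and DISC1. Reads they share may have been counted more than once. Shuffling the gene order parts such neighbours, so the shuffles below may understate what chance gives. In windows of 20 genes stepping by 5, with symbols matched by name alone, the matching used first, 30 of 1000 shuffles of the gene order reached the highest median of 0.136 (highest shuffle 0.162). With older symbols matched too, which also moved the window starts, 0 of 1000 reached 0.225 (highest 0.163). With windows starting at every gene, tried last, 0 of 1000 shuffles reached the highest median under either matching, 0.188 by name alone (highest shuffle 0.157) and 0.225 with older symbols (highest 0.158). Windows as long as the block, tried before that, gave 0.129 against a highest shuffle of 0.0930. A gain of 1 copy in every cell of a diploid line would give 0.585, above the upper quartile of 0.244. The lowest knockout library lay 0.0965 above the highest wild-type library in the block, but the block was picked because its genes were higher in the knockout, so this separation says nothing for or against a cause. A gain in part of the knockout cells cannot be told apart from coordinated regulation, as DNA was not analysed here.

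The lowest window of 20 genes lay at the start of chromosome 1, from 14404 to 1402046, with a GC-corrected median of -0.188 and 0 genes above 0. The next lowest windows overlapped it, at -0.138 and -0.132. In size -0.188 exceeds 0.163, the highest median of the 1000 shuffles used for high windows. No shuffle of low windows is given, so chance was not tested here. Distal 1q was thus not the only region with an extreme window.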
